A study of Arabidopsis thaliana with 2 samples.

How the data were processed

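Seedling RNA was profiled on 2 Agilent two-colour oligonucleotide arrays of design 021169. Each array held Cy5-labelled cRNA from goniothalamin-treated seedlings and Cy3-labelled cRNA from control seedlings, and per the labels these are 2 biological replicates of each condition. Both arrays sat on 1 slide and were scanned together, so slide and scan are shared. There was no dye swap. Labelling started from 500 ng of total RNA with an oligo(dT) primer, per the labels' protocols. The label protocol names another compound for the Cy5 sample than the sample titles do, and the titles were followed. A 2 h time point that the labels mention is not analysed here.

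The deposited scanner files give spot intensity in both channels, with background intensity and flags, as written by Feature Extraction 10.5.1.1 under extraction protocol GE2_105_Dec08, per the file headers. The submitters' processing notes name Agilent Feature Extraction 8.5.1.1. The deposited table of the series holds log10 ratios of Cy5 over Cy3, a scale and direction found by setting it against the scanner's own log ratio: r across spots was 0.99993 on the replicate 1 array and 0.999999 on the replicate 2 array. It differed by more than 0.0051 at 5 spots of the replicate 1 array (at most 0.528) and at 0 spots of the replicate 2 array, and its median was 0 on both. It lacks 56 and 35 values. Flags mark spots as outlying, saturated or well above background, per the file headers; 0 spots were saturated.

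Of 45220 spots per array, 43803 were not controls, from 43603 distinct probes with a median length of 60 bases. By locus codes in the file's systematic names and accessions, 37540 probes matched 1 locus, 873 several and 5190 none. The probes cover 29015 loci, of which 28580 were found in a RefSeq gene table of assembly TAIR10.1, used for names only. Background was corrected with normexp at an offset of 50, ratios were normalized within each array by loess with control spots at weight 0, spots flagged as outliers were left out (32 and 16 non-control spots), and spots of a probe were averaged. A gene was represented by its brightest probe with 1 locus, or by a shared probe where it had no other (286 of the genes tested). Among 5764 loci with several measured probes, 2 had probes that were at least 2-fold apart from 0 in opposite directions. A gene was tested if its probe was well above background in Cy5 on both arrays or in Cy3 on both arrays, which left 20661 genes.

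Log2 ratios were tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit with an intercept only, then eBayes) and Benjamini-Hochberg adjustment. The tests are two-sided. A gene was called at an adjusted p under 0.05 and an absolute log2 ratio of at least 1. With 2 arrays there is 1 residual degree of freedom, to which eBayes added 3.43, and the smallest adjusted p was 0.000717. The median standard error was 0.151 on the log2 scale. Gene lists with at least 5 tested members were tested with camera at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over 36 lists. Of these, 20 passed, and 0 did when camera estimated the correlation, which rests on the same residual degree of freedom. In that setting even the heat shock list, with all 31 members higher, had an unadjusted camera p of 0.24. Its adjusted p of 0.778 was the same for every list that had passed. The setting therefore cannot decide for or against a single list. A gene not well above background in the dimmer channel on either array was given a lower bound of its fold, computed per channel after loess and Aquantile normalization from the mean of the arrays, so 1 array alone can lie below it. The dim channel was raised only to the lowest signal that was well above background, so a bound can equal the ratio itself. Other processing can give a smaller fold.

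The tests, the gene lists, the naming rule and most alternatives were fixed before the data were examined. The rule named, among called genes with the same sign on both arrays, 1 locus per probe and signal well above background in both channels, the 10 highest and 10 lowest by the smaller absolute log2 ratio of the arrays. It added the 3 highest and 3 lowest lower bounds, and up to 4 called genes from each list that passed or had at least 3 called members. The values of 1 gene that the rule named are not reported here. The lists covered heat shock, proteasome, unfolded protein response, electrophile response, glutathione S-transferases, antioxidants, sulfur, hormones, defence, low oxygen, senescence, clock, nutrients, photosynthesis, chlorophyll, growth, secondary metabolism, organelle genes and cell-type markers. Members were chosen from textbook knowledge and were not checked against a database.

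The steps were tested on simulated ratios for the 20661 genes of this comparison, with 50 genes changed at each fold. Of genes changed 2-fold, 2 of 50 were recovered, and 44 of 50 at 4-fold, 50 of 50 at 8-fold and 50 of 50 at 16-fold, with 14 false calls among 20431 unchanged genes. A true 2-fold change sits on the call minimum, which by itself holds recovery down. The simulation drew genes independently and changed 200 at these folds, against 4759 called in the data. Its rates therefore need not hold for this comparison. Alternatives covered background correction, scaling, the filter on dim probes, the choice of probe, separate channels, GC content, the variance model, the threshold, camera's correlation and leaving out each array.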

Results

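Transcript levels were measured in Arabidopsis thaliana seedlings of the Col-0 accession treated with goniothalamin, a styryl lactone made by plants of the genus Goniothalamus. Seedlings aged 14 days were moved from agar into water and then into 20 ml of deionized water with 100 ppm goniothalamin and 1% dimethyl sulfoxide, and were collected after 6 h in the light. Control seedlings were collected at 0 h. Each of 2 microarrays compared 1 treated sample, labelled with Cy5, with 1 control sample, labelled with Cy3, and the labels call these pairs biological replicates. Signal was well above background for 30767 of 43803 spots in the treated channel and 29547 in the control channel on the replicate 1 array, and for 30451 and 30138 on the replicate 2 array. The number of arrays limits the precision of every value below. All log2 ratios are treated over control. An error after a log2 ratio is limma's standard error after eBayes, with n = 2 arrays. It also draws on the spread of all genes. It can therefore be larger or smaller than the 2 arrays of that gene alone would give.

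The comparison asks which transcripts differ between seedlings after 6 h with goniothalamin and seedlings at 0 h. Transcripts of heat shock proteins showed the largest rises, reaching about 352-fold for HSP70B, while most genes on the lists of expansins, auxin response, aliphatic glucosinolate synthesis and root markers were lower. Of 20661 genes tested, 4759 changed (limma, adjusted p under 0.05 and at least 2-fold), 2633 of them higher and 2126 lower in treated seedlings. Large changes were mostly rises: 316 genes were at least 8-fold higher and 28 at least 8-fold lower, and 61 were at least 32-fold higher against 0 lower. These counts depend on the processing: with the scanner's processed signals, 602 genes were at least 8-fold higher and 303 lower, and 125 at least 32-fold higher against 12 lower. The split between higher and lower calls depends on the scaling: with median centring in place of intensity-dependent loess, 1670 genes were higher and 4231 lower. Treatment, dye, time of day, solvent and the move into water all differ between the 2 channels in the same way on both arrays, so the ratios hold their joint effect. The size of single ratios depends on the processing too. Of the 144 genes named by rule, 40 moved by over 1.5-fold with the scanner's processed signals.

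The arrays gave similar ratios. Pearson's r between them was 0.896 across the 20661 genes, which are not independent replicates, and 86.5% of genes had the same sign on both. In all, 2169 genes were at least 2-fold higher on each array and 1446 at least 2-fold lower on each.

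**Figure D1:**
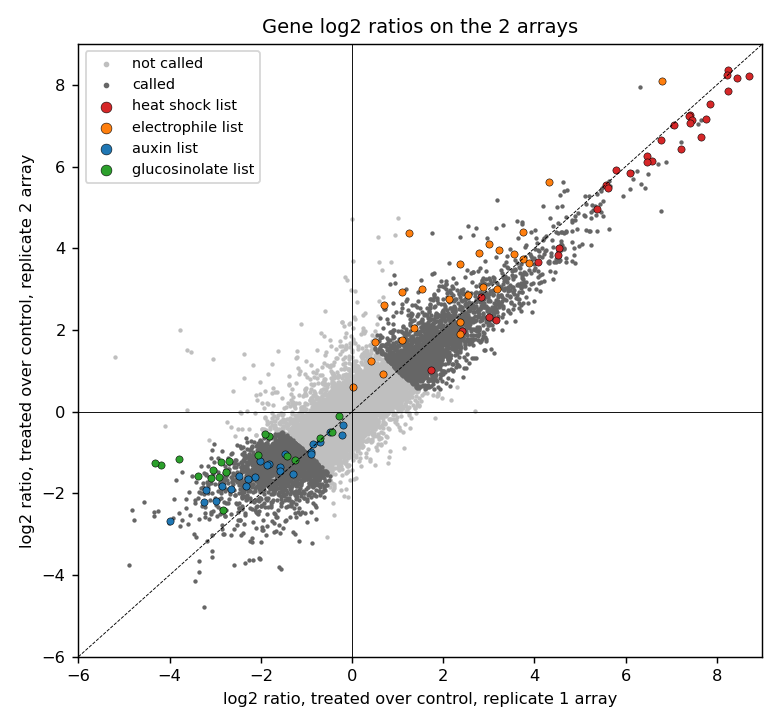
Log2 ratio of each tested gene, treated over control, on the replicate 1 array (x axis) and the replicate 2 array (y axis), with called genes in dark grey and members of 4 gene lists in colour; the dashed line marks equal ratios. The 31 heat shock genes range from 1.37 to 8.46 in mean log2 ratio, with a median of 6.36. The 19 glucosinolate genes lie mostly above the dashed line at negative ratios.

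All 31 tested members of the heat shock list were higher in treated seedlings, with a median log2 ratio of 6.36 (6.57 on the replicate 1 array and 6.27 on the replicate 2 array). The list passed camera's test (adjusted p = 1.2e-21 with a preset correlation; adjusted p = 0.778 with an estimated correlation). HSP90.1, a cytosolic chaperone, had a log2 ratio of 8.30 ± 0.14 (315-fold, limma adjusted p = 0.000717), while another probe for it gave 5.71 and the mean of its probes 7.004. The probe for HSP90.1 lies on chromosome 5 at 21372227 to 21372286 in the ath1:Jan2004 build named in the file header. HSP70B rose by 8.46 ± 0.18 and HSP70 by 7.68 ± 0.16 on the log2 scale. Small heat shock proteins rose alongside them, with log2 ratios of 8.31 ± 0.16 for HSP26.5, 8.24 ± 0.14 for HSP17.6B, 8.05 ± 0.17 for HSP22, 7.34 ± 0.15 for HSP17.4, 7.32 ± 0.14 for HSP17.6II and 7.40 ± 0.18 for AT1G59860, which the array annotates as a class I small heat shock protein. With the scanner's processed signals, HSP22, HSP17.4 and HSP17.6II had 9.95, 8.202 and 8.29. ROF2, an FK506-binding peptidyl-prolyl isomerase, had a log2 ratio of 7.46 ± 0.20. These 9 chaperone genes and ROF2 are the 10 highest genes under the naming rule. AT1G71000, annotated as a DNAJ-domain protein, was not well above background in the control channel and was at least 151-fold higher in treated seedlings (limma adjusted p = 0.000717). HA9, a plasma membrane proton pump, was at least 23.7-fold higher and AT5G53680, an RNA recognition motif protein, at least 10.02-fold higher by the same measure, which is open to dye bias because dyes were not swapped. The bounds are means over the arrays, and 1 array lay below each: log2 ratios were 7.05 on the replicate 2 array for AT1G71000, 4.19 on the replicate 1 array for HA9 and 3.01 on the replicate 2 array for AT5G53680. Other processing also went below them, with lowest log2 ratios over the settings of 6.94 for AT1G71000, 4.15 for HA9 and 3.08 for AT5G53680.

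**Figure D2:**
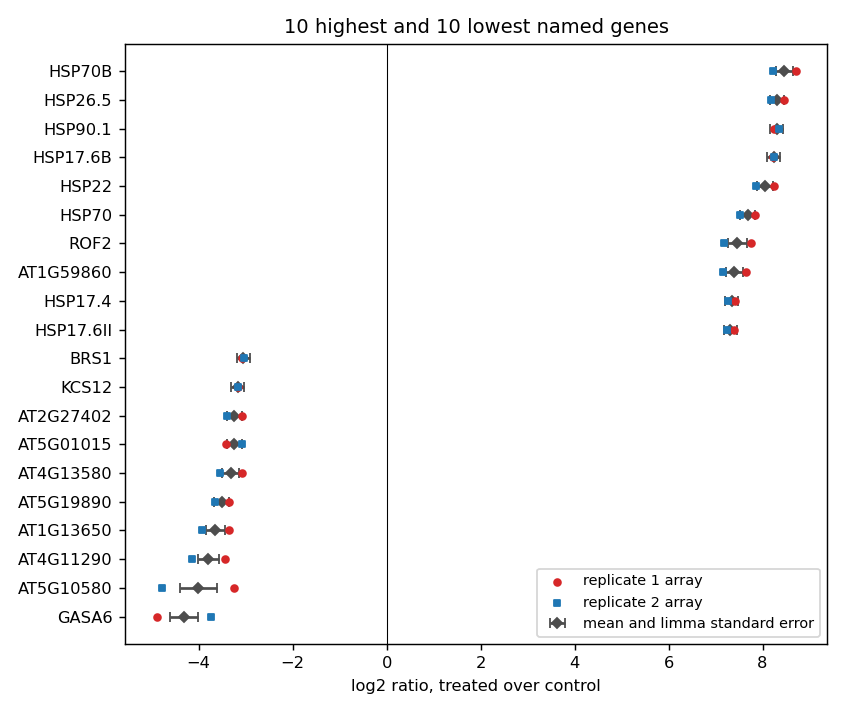
Log2 ratio, treated over control (x axis), of the 10 highest and 10 lowest genes under the naming rule, with 1 point per array and the mean with limma's standard error (n = 2 arrays). HSP70B lies highest at 8.46 and GASA6 lowest at -4.31.

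Other lists of protein quality control moved the same way. Of 35 tested genes for proteasome subunits and their NAC regulators, 23 were higher and 0 lower, with a median log2 ratio of 1.29 (camera adjusted p = 3.11e-12; adjusted p = 0.778 with an estimated correlation). NAC053 and NAC078, transcription factors that activate proteasome genes, rose by 3.36 ± 0.15 and 2.93 ± 0.21 on the log2 scale, and the subunit genes RPT3 and RPT2A by 2.87 ± 0.15 and 2.31 ± 0.14. Of 18 genes of the endoplasmic reticulum unfolded protein response, 12 were higher and 0 lower, with a median of 1.36 (camera adjusted p = 2.25e-07; adjusted p = 0.778 with an estimated correlation). The chaperone genes ERDJ3A and BIP3 rose by 5.06 ± 0.16 and 4.56 ± 0.14, the transcription factor gene BZIP60 by 2.71 ± 0.14 and the disulfide isomerase gene PDIL1-2 by 2.31 ± 0.14. ERDJ3A and BIP3 had 5.67 and 5.97 with the scanner's processed signals, and NAC078 had 2.304 with the mean of its probes.

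Of 26 tested genes on the list of xenobiotic and electrophile response, 23 were higher and 0 lower, with a median log2 ratio of 2.76 (camera adjusted p = 7.66e-11; adjusted p = 0.778 with an estimated correlation). ABCG40, a plasma membrane transporter, had a log2 ratio of 7.44 ± 0.33 (174-fold), the cytochromes P450 CYP81D8 and CYP81D11 had 4.97 ± 0.34 and 4.07 ± 0.21, and NDB2, a mitochondrial NAD(P)H dehydrogenase, had 3.74 ± 0.14. The 38 tau and phi glutathione S-transferases went both ways, with 19 higher, 9 lower and a median of 0.95, and the list did not pass (camera adjusted p = 0.105). GSTU19 rose by 5.43 ± 0.14, GSTU24 by 5.13 ± 0.27, GSTF8 by 4.27 ± 0.14 and GSTU7 by 4.16 ± 0.25. GSTU20, chosen after its value was seen, fell by 2.32 ± 0.49 on the log2 scale. Of 19 antioxidant and oxidative stress genes, 7 were higher and 0 lower (median 0.50, camera adjusted p = 0.0139; adjusted p = 0.778 with an estimated correlation), among them the zinc finger gene ZAT12 at 5.61 ± 0.21, GPX6 at 3.495 ± 0.14, TRXH5 at 3.07 ± 0.26 and DHAR2 at 2.96 ± 0.16. Of 23 genes of sulfur assimilation and glutathione synthesis, 6 were higher and 2 lower (median 0.16, camera adjusted p = 0.428), with APR3 at 3.07 ± 0.24, SERAT2;1 at 2.54 ± 0.14, LSU1 at 2.402 ± 0.16 and APR1 at 2.37 ± 0.28. Some of these values varied. ABCG40 had 6.81 and 8.08 on the arrays and 8.08 with the scanner's processed signals, and CYP81D8 had 4.32 and 5.62 on the arrays. GSTU19 had 4.80 with median centring and LSU1 1.70 with the mean of its probes.

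Of 22 salicylate genes, 13 were higher and 1 lower, with a median log2 ratio of 1.11 (camera adjusted p = 0.000357; adjusted p = 0.778 with an estimated correlation). The glutaredoxin gene GRX480 rose by 5.07 ± 0.22 (2.77 with the mean of its probes), and WRKY54, WRKY40 and WRKY33 by 2.23 ± 0.14, 2.21 ± 0.18 and 2.01 ± 0.15. Of 16 low-oxygen genes, 10 were higher and 1 lower (median 1.33, camera adjusted p = 0.00345; adjusted p = 0.778 with an estimated correlation), including SRO5 at 4.66 ± 0.31, the transcription factor gene HRE2 at 3.46 ± 0.14 (well above background in the control channel on 1 array, 6.08 with the scanner's processed signals), and the pyruvate decarboxylase genes PDC2 at 3.34 ± 0.14 and PDC1 at 2.27 ± 0.14. Of 13 senescence genes, 7 were higher and 1 lower (median 1.36, camera adjusted p = 0.0138; adjusted p = 0.778 with an estimated correlation), including SAG13 at 3.60 ± 0.45, WRKY75 at 3.53 ± 0.31, SAG21 at 3.304 ± 0.23 and PPH at 1.86 ± 0.14. Of 26 clock and clock output genes, 13 were higher and 4 lower (median 0.77, camera adjusted p = 0.0246; adjusted p = 0.778 with an estimated correlation). LUX, ELF4 and PRR5 rose by 3.46 ± 0.20, 3.01 ± 0.17 and 2.95 ± 0.17, while COL2 fell by 3.39 ± 0.47. Between the arrays, COL2 had -4.33 and -2.45, SAG13 2.71 and 4.49, and WRKY75 4.12 and 2.94. The call for COL2 was lost without the filter on dim probes (adjusted p = 0.0582). With the scanner's processed signals, WRKY54 had 2.90, SRO5 5.499 and SAG13 4.80.

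Of 24 early auxin response genes, 17 were lower and 0 higher, with a median log2 ratio of -1.56 (camera adjusted p = 1.21e-08; adjusted p = 0.778 with an estimated correlation). The Aux/IAA repressor genes IAA2, IAA3 and IAA4 fell by 3.33 ± 0.34, 2.72 ± 0.28 and 2.59 ± 0.24 on the log2 scale, and PIN3, an auxin efflux carrier gene, fell by 2.56 ± 0.33. Of 24 expansin and xyloglucan-modifying enzyme genes, 15 were lower and 2 higher (median -1.83, camera adjusted p = 0.000272; adjusted p = 0.778 with an estimated correlation). EXPA1, EXPA8 and EXPA6 had log2 ratios of -3.72 ± 0.53, -3.37 ± 0.33 and -3.26 ± 0.34, and XTH23 went the other way at 3.45 ± 0.20. Of 30 cell cycle genes, limma called 0 in either direction, with 16 at an unadjusted p under 0.05. With no fold minimum, 8 were lower and 0 higher at a limma adjusted p under 0.05. The list passed (median -0.52, -0.25 and -0.77 on the arrays, camera adjusted p = 0.000717, and adjusted p = 0.778 with an estimated correlation). Of 187 cytosolic ribosomal protein genes, 7 were lower and 1 higher (median -0.37, -0.15 and -0.57 on the arrays, camera adjusted p = 1.1e-05; adjusted p = 0.778 with an estimated correlation). The 1 higher gene, SAG24, annotated as a 60S ribosomal protein L10 gene, had a log2 ratio of 4.50 ± 0.15. Of 10 root markers, 8 were lower and 0 higher (median -1.22, camera adjusted p = 0.000195; adjusted p = 0.778 with an estimated correlation), with the endodermal genes ESB1 and CASP1 at -2.44 ± 0.15 and -2.23 ± 0.17 and EXPA7, well above background in the treated channel on 1 array, at -1.41 ± 0.18 (-3.73 with the scanner's processed signals). These signals moved list medians too, to -2.82 for auxin response, -2.51 for expansins and xyloglucan-modifying enzymes and -2.32 for root markers. They gave -3.47 for IAA3, -3.31 for PIN3 and -2.84 for CASP1. The arrays differed for IAA2 (-3.99 and -2.67), PIN3 (-3.20 and -1.92), EXPA1 (-4.79 and -2.64), EXPA8 (-4.00 and -2.73) and EXPA6 (-3.92 and -2.61). Calls were lost without the filter on dim probes for PIN3 (adjusted p = 0.0507) and EXPA1 (adjusted p = 0.0614). EXPA8 had -2.42 with the mean of its probes and SAG24 3.90 with median centring.

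The 10 lowest genes under the naming rule were led by GASA6, a gibberellin-responsive gene, with a log2 ratio of -4.31 ± 0.31 (19.9-fold lower, limma adjusted p = 0.00273). Its probe lies on chromosome 1 at 28057480 to 28057539 in the ath1:Jan2004 build. AT4G11290 and AT5G19890, both annotated as peroxidases, had -3.79 ± 0.22 (-2.89 with the mean of its probes) and -3.505 ± 0.16 (-4.91 with the scanner's processed signals). AT5G10580, of unknown function, had -4.01 ± 0.39 (-3.24 and -4.78 on the arrays), and AT1G13650, which the array annotates as similar to a pre-ribosomal assembly protein, had -3.64 ± 0.20. These were -5.68 and -5.45 with the scanner's processed signals. KCS12, a ketoacyl-CoA synthase gene, had -3.17 ± 0.14, and BRS1, a carboxypeptidase gene, had -3.05 ± 0.14 (-3.68 with the scanner's processed signals). AT4G13580, AT5G01015 and AT2G27402 had -3.31 ± 0.18, -3.24 ± 0.16 and -3.24 ± 0.16 (-4.23, -4.02 and -3.98 with those signals). Among genes not well above background in the treated channel, CYP702A5 was at least 4.66-fold lower, GH9C1 at least 3.18-fold lower and AT2G35380 at least 2.93-fold lower by the mean of the arrays. The replicate 1 array lay below each of these bounds, with log2 ratios of -1.57 for CYP702A5, -1.44 for GH9C1 and -1.06 for AT2G35380. CYP702A5 had -1.63 with the mean of its probes. Without the filter on dim probes, calls were lost for CYP702A5 (adjusted p = 0.0686) and AT2G35380 (adjusted p = 0.0774).

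Of 19 genes of aliphatic glucosinolate synthesis, 16 were lower and 0 higher, with a median log2 ratio of -2.05 that differed between the arrays, -2.76 and -1.21 (camera adjusted p = 1.1e-05; adjusted p = 0.778 with an estimated correlation). MAM3 fell by 2.62 ± 0.17, IPMI2 by 2.48 ± 0.45, IMD1 by 2.36 ± 0.38 and BAT5 by 2.26 ± 0.34. Of 14 chlorophyll synthesis genes, 7 were lower and 0 higher (median -0.92, camera adjusted p = 0.000149; adjusted p = 0.778 with an estimated correlation), including CHLM at -1.92 ± 0.23, PORC at -1.61 ± 0.17, GSA2 at -1.47 ± 0.15 and CHLG at -1.36 ± 0.14. Of 46 nuclear photosynthesis genes, 8 were lower and 0 higher, with medians of -0.79 and -0.11 on the arrays (camera adjusted p = 0.00681; adjusted p = 0.778 with an estimated correlation). RBCS1B, LHCB2.3, PRK and RBCS2B fell by 2.21 ± 0.15, 2.53 ± 0.48, 1.62 ± 0.28 and 1.61 ± 0.18. The photosynthesis call was lost with the scanner's processed signals (median -0.32, adjusted p = 0.192) and with the series table (median -0.37, adjusted p = 0.11). Of 66 plastid-encoded genes, 3 were lower and 0 higher (median -0.51, -0.60 and -0.32 on the arrays, camera adjusted p = 0.000104; adjusted p = 0.778 with an estimated correlation). Labelling used an oligo(dT) primer, so these ratios may not follow total plastid transcript levels, and 10 of the 66 rest on shared probes. Of 12 flavonoid genes, 5 were lower and 0 higher (median -0.81, camera adjusted p = 0.0131; adjusted p = 0.778 with an estimated correlation), including CHS at -1.82 ± 0.22 and FLS1 at -1.74 ± 0.28. Of 17 phenylpropanoid genes, 7 were lower and 1 higher (median -0.71, camera adjusted p = 0.0209; adjusted p = 0.778 with an estimated correlation). PAL3 and CAD4 fell by 2.18 ± 0.26 and 2.03 ± 0.24, and the 1 higher gene, CAD5, had 2.02 ± 0.20. Several of these values depend on the array or the processing. IPMI2 had -3.38 and -1.58 on the arrays, IMD1 -3.09 and -1.62, BAT5 -2.92 and -1.61, and LHCB2.3 -3.502 and -1.57. Without the filter on dim probes, calls were lost for IPMI2, IMD1, BAT5, LHCB2.3, PRK and FLS1 (adjusted p = 0.0870, 0.0690, 0.0624, 0.0932, 0.0713 and 0.0660). Median centring put the photosynthesis median at -1.19, RBCS1B at -2.95, LHCB2.3 at -3.12 and RBCS2B at -2.41. The scanner's processed signals put the flavonoid median at -1.69 and BAT5 at -3.03, and the mean of its probes put BAT5 at -1.66.

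**Figure D3:**
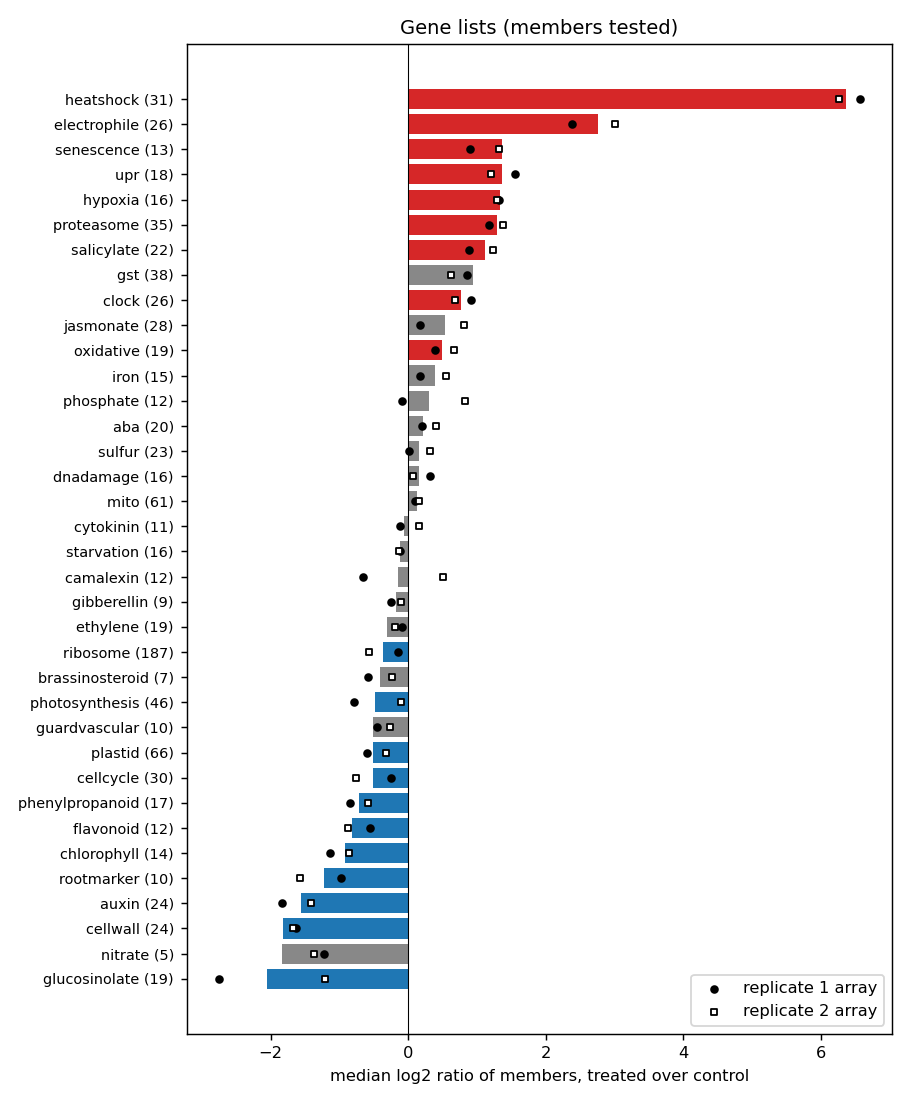
Median log2 ratio, treated over control (x axis), of the tested members of each of the 36 gene lists (bars, with the number of members tested), with the median on each array as points; red bars passed camera's test upward, blue bars downward and grey bars did not pass. The heat shock list stands highest at 6.36 and the glucosinolate list lowest at -2.05.

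The remaining lists did not pass camera's test as processed here, though 7 lists that did not pass, glutathione S-transferases among them, did in at least 1 other setting. Of 28 jasmonate genes, 7 were higher and 2 lower (median 0.54, 0.18 and 0.81 on the arrays, camera adjusted p = 0.065), among them JAZ10 at 2.21 ± 0.23 and OPR3 at 2.09 ± 0.18. Of 20 abscisic acid and drought genes, 7 were higher and 0 lower (median 0.21, adjusted p = 0.0789), including COR47 at 3.08 ± 0.33 and ERD14 at 2.32 ± 0.18. Of 16 DNA damage genes, 4 were higher and 0 lower (median 0.16, 0.32 and 0.07 on the arrays, adjusted p = 0.138), with the cell cycle inhibitor genes SMR5 and SMR4 at 4.23 ± 0.26 and 2.91 ± 0.35 and AGO2 at 3.66 ± 0.14. Of 12 phosphate starvation genes, 4 were higher and 1 lower (median 0.30, -0.10 and 0.83 on the arrays, adjusted p = 0.398), led by PS2 at 4.17 ± 0.50. Of 15 iron genes, 2 were higher and 3 lower (median 0.39, adjusted p = 0.681), with the ferritin genes FER1 and FER3 at -2.48 ± 0.14 and -1.51 ± 0.21. Of 5 nitrate genes, 3 were lower and 0 higher (median -1.84, -1.22 and -1.36 on the arrays, adjusted p = 0.246): NRT1.1 at -1.96 ± 0.31, NRT2.1 at -1.90 ± 0.35 and NIR1 at -1.84 ± 0.19. Of 19 ethylene genes, 2 were higher and 4 lower (median -0.32, adjusted p = 0.371), with ACO1 at -1.78 ± 0.14. Of 11 cytokinin genes, 3 were higher and 0 lower (adjusted p = 0.681), with ARR5 at 2.06 ± 0.17, and the median of -0.07 (-0.12 and 0.16 on the arrays) and mean of 0.34 differed in sign. Of 16 sugar starvation genes, 3 were higher and 1 lower (adjusted p = 0.979), with DRM2 at 1.99 ± 0.14, and the median of -0.12 and mean of 0.09 differed in sign. Of 9 gibberellin genes, 1 was higher and 2 lower (median -0.18, adjusted p = 0.621), and of 7 brassinosteroid genes, 1 was lower and 0 higher (median -0.41, adjusted p = 0.113). Of 12 camalexin and indole glucosinolate genes, limma called 0, with 2 at an unadjusted p under 0.05 (median -0.15, -0.66 and 0.51 on the arrays, camera adjusted p = 0.979). With no fold minimum, 1 of them was higher and 0 lower at a limma adjusted p under 0.05. Of 10 guard cell and vascular markers, 1 was lower and 0 higher (median -0.51, adjusted p = 0.0593), and of 61 mitochondrially encoded genes, 3 were higher and 0 lower (median 0.13, adjusted p = 0.17). The mitochondrial ratios share the limit of the oligo(dT) primer, and 6 of the 61 genes rest on shared probes. Several of these values depend on the array or the processing. PS2 had 3.18 and 5.17 on the arrays and 3.24 with the mean of its probes. On the arrays, NRT1.1 had -2.55 and -1.36, NRT2.1 -1.22 and -2.57, COR47 3.70 and 2.46, and SMR4 3.58 and 2.23. Without the filter on dim probes, the nitrate median was -0.91, and calls were lost for NRT1.1 (adjusted p = 0.0667) and NRT2.1 (adjusted p = 0.0850). NRT2.1 had -3.60 with the scanner's processed signals and -2.67 without background correction. The same signals gave 3.83 for SMR4, -2.398 for ACO1 and a gibberellin median of -0.77. Median centring gave 2.42 for COR47, 1.65 for ERD14 and 1.34 for DRM2, which had 1.37 with the mean of its probes. Adjusted over the list alone, the counts were the same in each list except for ethylene (0 higher, 3 lower), sulfur (7 higher, 2 lower) and ribosomal protein genes (1 higher, 0 lower).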

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

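The tests on other probes, clock phase, dim clock probes and the spread of root markers were chosen after the results were seen.

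Probes without a locus code as their systematic name were outside the comparison of genes. Descriptions of some such probes do name a gene, such as PMZ for CB185540 and At1g67360 for TC300093, so they are not all unannotated transcripts. Of 2361 such probes tested, 204 were higher and 112 lower in treated seedlings by the same thresholds (limma, adjusted over these probes), which puts treated signal above the control channel for the former.

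All 31 heat shock genes rose, with a median log2 ratio of 6.36. Against sequence bias or cross-hybridization of the chosen probe, 7 other probes gave log2 ratios of at least 3.94. They cover only BAG6, DREB2A, FES1A, GOLS1 and HSP90.1, and for HSP90.1 the other probe gave 5.71 against 8.30. The small heat shock protein and HSP70 genes named above are not covered, so for them this explanation stays open. Without background correction, the list median was 6.52. That cannot decide on low control signal, since a raw control background of 34 and 35.5 then takes the place of the offset of 50. In every setting that kept both arrays the list median was 6.02 to 6.66, also with signal well above background in both channels required. Transfer to water, solvent and elapsed time instead of the compound cannot be told apart from it, since 0 arrays had a control taken at 6 h. A gene-specific dye effect was not tested, as dyes were not swapped.

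Clock genes moved apart by phase. The median log2 ratio of 11 evening-phased genes was 1.83 and that of 10 morning-phased genes -0.44, a difference of 2.26 (two-sided permutation test over genes, p = 0.00039, 100000 resamples; genes are not independent). A later time of day of the treated plants may explain this, since controls were taken at 0 h. Within the morning set, LNK1, CCA1 and PRR9 had ratios above 0, at 1.09, 0.45 and 0.09. Phases were assigned from textbook knowledge to 21 of the 26 tested clock genes, for a test chosen after the results were seen. Against dim probes of clock genes, all 21 genes were well above background in both channels, so 0 were dim. An effect of the compound on the clock stays open.

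Root markers fell, with a median of -1.22. PRP3 at -0.20 and ESB1 at -2.44, the highest and lowest reported markers with clear signal, differed by 2.24 (standard error 0.203). The pair was picked as the extremes, which the standard error does not allow for. Markers need not fall equally when root RNA falls, so this cannot decide on a lower root share as the whole cause. Against low signal of the root marker probes, the median was -1.22 among the 8 markers well above background in both channels. A change in root share, alone or together with changes in single genes, stays open.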

How the results depend on the processing

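Centring on spike-in controls and testing all probes separately were chosen after seeing the data. Among 144 named genes, 0 changed sign in any setting. The naming rule required the same sign on both arrays, so leaving out an array could not turn a sign. Calls were lost for 22 without the filter on dim probes, 7 with median centring and at most 3 in any other setting. Of the 144, 133 could be tested where signal had to be well above background in both channels on both arrays. Counts of changed genes moved by over 1.5 times in these settings: median centring gave 1670 higher and 4231 lower genes (28.3% higher against 55.3%) and put the median of all genes at -0.35 instead of -0.04; the scanner's processed signals gave 7465 changed and 4031 lower; the series table gave 7444 and 4023; and an adjusted p under 0.05 with no fold minimum gave 9311. The cause was not tested. Camera with an estimated correlation called 0 lists, and 0 had an unadjusted p under 0.05 (smallest 0.105). It rests on 1 residual degree of freedom and gave 0.24 even for the heat shock list, so it cannot decide on single lists. On 1 array alone, 4034 to 4339 of the 4759 called genes were still at least 2-fold in their direction, as a value with no test. The genes were called on the mean of the same arrays, so these counts do not measure independent replication. The arrays pair the channels; separate channels with no replicate block called 4585 genes and the pairing changed the list calls only for guard cell and vascular markers. Centring on spike-in controls subtracted the scanner software's spike-in intercepts, which were not computed from the loess-normalized ratios used here. It set the arrays 0.34 apart on the log2 scale, so its p-values rest on a pooled spread. Camera's direction, but not the median's sign, turned for lists that passed in no setting: sugar starvation, with medians of -0.12 (offset 16, no background correction, no filter, separate channels), -0.58 (median centring), -0.25 (series table), -0.13 (mean of probes and spike-in centring) and -0.11 (GC), camalexin at -0.12 (no filter) and iron at 0.38 (spike-in centring). Of lists that did not pass, 7 passed in other settings: jasmonate in 4 (lowest adjusted p = 0.0299), guard cell and vascular markers in 4 (0.0232), mitochondrial genes in 3 (0.0046), abscisic acid in 2 (0.0332; with median centring at a median of -0.06), glutathione S-transferases in 2 (0.0028 with median centring and 8.22e-07 with spike-in centring) and DNA damage and nitrate in 1 each (spike-in centring). The medians of 9 lists without replicate 1 and 6 without replicate 2 moved by more than the spread between arrays. The medians of 7 lists moved by over 1.5-fold in at least 1 setting that kept both arrays, and the largest move was for auxin response, to -2.82 with the scanner's processed signals and with the series table. Of the 144 named genes, 56 moved by over 1.5-fold in at least 1 setting: 40 with the scanner's processed signals, 40 with the series table, 17 without background correction, 10 with the mean of probes, 9 with median centring and 1 at an offset of 16. Signal over background limits dim genes to lower bounds, which were computed under the main processing only.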

Other observations

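Families taken from the array's descriptions were chosen after seeing the data, and none passed camera with an estimated correlation (smallest adjusted p = 0.374). That setting cannot decide on single families either. With the preset correlation, DNAJ, lipid transfer, F-box and leucine-rich repeat proteins passed but are not detailed below. MATE transporters, UDP-glycosyltransferases, tubulins and pentatricopeptide repeat proteins did not pass (camera adjusted p = 0.544, 0.544, 0.193 and 0.0798). Of 218 genes described as ubiquitin or ubiquitin ligases, 62 were higher and 5 lower (median log2 ratio 0.52, camera adjusted p = 1.07e-06), with UBQ3 at 4.81 ± 0.23 and the conjugating enzyme genes UBC11 and UBC31 at 4.02 ± 0.14 and 3.53 ± 0.14. Of 59 NAC transcription factor genes, 19 were higher and 0 lower (median 0.41, adjusted p = 0.00277), with NAC004 at 4.11 ± 0.16 and ATAF2 at 3.59 ± 0.16. Of 64 WRKY genes, 22 were higher and 2 lower (median 0.19, adjusted p = 0.00668), with WRKY46 at 3.16 ± 0.27. WRKY50, not well above background in the control channel, was 7.60-fold higher, where the lower bound equals the ratio. Of 24 microRNA precursors, 7 were higher and 0 lower (median 0.38, adjusted p = 0.0123), with MIR156c at 2.89 ± 0.14 and MIR172a, not well above background in the control channel, at least 8.66-fold higher.

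Of 27 aquaporin genes, 13 were lower and 0 higher (median -0.89, camera adjusted p = 2.37e-05), with DELTA-TIP, TIP2;2 and PIP2B at -3.17 ± 0.25, -2.57 ± 0.23 and -2.48 ± 0.18. Of 71 genes described as peroxidases, 30 were lower and 7 higher (median -0.87, adjusted p = 0.000219). Of 33 histone genes, 9 were lower and 2 higher (median -0.39, adjusted p = 0.0209). Of 130 transposable element genes, 8 were higher and 4 lower (median 0.13, adjusted p = 0.0798). Root markers, at a median of -1.22, moved with the aquaporin and peroxidase genes.

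By the scanner software's fit against their expected ratios, the spike-in controls had an intercept of -0.16 on the replicate 1 array and 0.18 on the replicate 2 array. These are on the log2 scale, and the slopes were 0.926 and 0.923.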
